A study of Mus musculus with 5 samples.

How the data were processed

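RNA of sorted mouse long-term haematopoietic stem cells (LT-HSCs) was hybridised to 5 Affymetrix mouse genome arrays, 2 from control and 3 from Lrf knockout animals. Per the labels' protocols, RNA was prepared with a microprep kit and biotin-labelled cRNA was made by 2 rounds of in vitro transcription. Repeated amplification of this kind shortens cRNA, so the signal comes mainly from the 3' ends of transcripts. The deposited values are log2 intensities, 1 per probe set and array, which the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions of these programs are not given in the sources used here. RMA subtracts background, forces all arrays to one distribution and combines the probes of a probe set, so a shift shared by most transcripts is removed and the dimmest and brightest values are compressed.

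The deposited table held 45101 rows, of which 64 were Affymetrix control probe sets and were left out of all tests except the check of RNA length. Of the remaining 45037 probe sets, the 40% with the lowest mean over all 5 arrays (below a log2 value of 5.77) were left out, and 27022 were tested. Gene names came from the platform annotation, which gave 34945 of these 45037 probe sets 1 gene symbol, gave 932 several symbols and left 9160 unnamed. No gene was named from a probe set with several symbols, except that adult globin probe sets shared by near-identical genes are given under all their symbols. A gene was represented by the probe set with the highest mean among those annotated to that gene alone, which gave 12813 genes. The number of arrays limits the precision of every difference reported.

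Knockout was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, no covariate, two-sided, Benjamini-Hochberg adjustment over the probe sets tested, adjusted p under 0.05). Standard errors (SE) are the moderated ones of this fit. Probe sets with an unadjusted p under 0.01 and a log2 difference of at least 1 in either direction were counted as candidates and are not called changed. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 31 lists with at least 3 genes tested. Camera with the correlation estimated from the data and fry were run beside it. The 32 lists held 596 entries, 545 of which matched a single-gene probe set and 497 of which passed the filter; the others were not analysed here. The lists covered Notch signalling, lymphoid, stem cell and other blood cell types, the cell cycle, interferon and stress responses, metabolism, ribosomes, stroma and sex-linked genes. Zbtb7a and the RNA length check were also tested with exact two-sided permutation tests, which with 2 against 3 arrays have 10 splits and a smallest p of 0.1. Figures were drawn with matplotlib 3.10.9.

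The lists, the tests, their alternatives and the rule for named genes were fixed before the data were examined. The rule takes Zbtb7a, then in each direction the 12 genes with the largest difference past the threshold and with groups that do not overlap. With fewer than 8 of these, a direction is filled to 8 with the genes of smallest unadjusted p among those whose groups do not overlap and whose log2 difference is at least 1, said not to pass. For each list described it adds up to 4 members with the smallest p, and for lists of other cell types the brightest members. Alternatives were another eBayes prior, no filter or a filter on the lowest 60%, array weights, cyclic loess, median centring, the mean of a gene's probe sets, a replicate block, and leaving out each array in turn. Only the knockouts had a replicate 3, so the replicate block gave the same differences as leaving out knockout replicate 3.

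The fit was tested on simulated data of the same size, with the spread of the real arrays and 50 probe sets changed at each of 4 log2 sizes. It recovered 4% of changes of size 1, 34% of size 2, 52% of size 3 and 74% of size 4, with 2 calls among 26822 unchanged probe sets. The simulated noise was independent between probe sets. The limma fit of the real arrays gave 306 probe sets with an unadjusted p under 0.05, where 1351 would be expected with no difference. The real data thus differ from the simulated setting, and these recovery rates may not hold for them.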

Results

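Loss of LRF, the transcription factor encoded by Zbtb7a, was studied in LT-HSCs of C57BL/6 mice aged 4 weeks. Cre recombinase under the Mx1 promoter was induced with 2 injections of the double-stranded RNA analogue pIpC (250 µg each), and cells were sorted on day 9 after the first injection. LT-HSCs were sorted as lineage-negative Sca-1-positive Kit-positive cells without IL7Ra, Flt3 or CD48 and with CD150. The labels gave 2 control mice with 1 floxed Zbtb7a allele and 3 knockout mice with both alleles floxed, all carrying Cre. The description of knockout replicate 3 named 2 animals and the others named 1 each, so whether each library came from a single mouse is not settled.

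The arrays had median log2 intensities of 6.38 to 6.40 and maxima of 15.19 to 15.29. Knockout replicate 2 stood apart: its correlation with the other arrays across 45037 probe sets, which are not independent replicates, was 0.945 to 0.970, against 0.977 to 0.990 for all other pairs. The difference between 3' and 5' probe sets of Actb was 3.85 in knockout replicate 2 and 4.90 to 5.21 elsewhere, and that of Gapdh was 4.67 against 5.06 to 5.17. Between the groups, the Actb difference was 4.98 ± 0.11 (SD, n = 2) in controls and 4.68 ± 0.73 (SD, n = 3) in knockouts (exact two-sided permutation p = 0.9, smallest possible 0.1). For Gapdh these values were 5.11 ± 0.07 and 4.97 ± 0.26 (exact permutation p = 0.9).

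Zbtb7a, the targeted gene, had 3 probe sets, none of which separated the groups. The brightest was 8.29 ± 0.10 (SD, n = 2) in controls and 8.70 ± 0.37 (SD, n = 3) in knockouts, a log2 difference of 0.41 (SE 0.26). The other 2 differed by -0.36 and -0.05. Exact two-sided permutation p-values were 0.3, 0.4 and 0.8, against a smallest possible 0.1. The labels do not say which part of the gene was deleted, and the positions of the probes were not analysed here, so these values check nothing about the deletion.

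The comparison of knockout with control asked how loss of Lrf affects the LT-HSC transcriptome. Since the controls also carried Cre and 1 floxed allele, effects of losing a single allele could not be seen. Transcripts of the embryonic globins Hbb-bh1 and Hba-x, which are normally made in primitive red cells of the embryo, were higher in all 3 knockout arrays than in both controls. Hbb-bh1 averaged 5.71 ± 0.73 (SD, n = 2) in controls and 11.78 ± 1.98 (SD, n = 3) in knockouts, a log2 difference of 6.07 (SE 1.23). The size of this difference is uncertain, since control replicate 2 read 5.20, below the level of 5.77 that was taken as near background. Hba-x averaged 7.01 ± 0.32 and 10.92 ± 1.28, a 15.1-fold difference (log2 3.92, SE 0.79). The groups did not overlap for 4 of 17 lymphoid progenitor genes, Rag1 among them, all higher in knockouts (23.5%, against 7.18% in either direction over 12813 genes and 20% by chance in either direction). Of 14 macrophage genes, 11 were lower in each knockout array than in both controls (78.6%), Axl and Cd163 among them. None of these single-gene differences passed the test over all probe sets.

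In the list of embryonic globins, both measured members passed when adjusted over the list alone (limma adjusted p = 0.00509), and 0 passed over all probe sets (adjusted p = 1). The other Hbb-bh1 probe sets differed by 5.70 and 3.78 (the latter from a control mean of 4.92, near background), and without knockout replicate 2 the difference of the brightest was 4.98. Without control replicate 2 the Hbb-bh1 and Hba-x differences were 5.55 and 3.69, with an adjusted p = 0.0554 over the list alone, which misses the threshold. The remaining gene of the list, Hbb-y, was dim in both groups (4.66 in controls and 4.78 in knockouts on its brightest probe set) and was left out by the filter. Adult globin transcripts did not follow the groups. The probe set shared by Hba-a1 and Hba-a2 read 15.13 in control replicate 1, 13.41 in control replicate 2, and 12.10, 15.19 and 12.56 in knockout replicates 1, 2 and 3. Probe sets whose names contain _x_at, among them those of Hbb-bh1, Trbv1 and Spic, can share probes with similar transcripts.

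**Figure D1:**
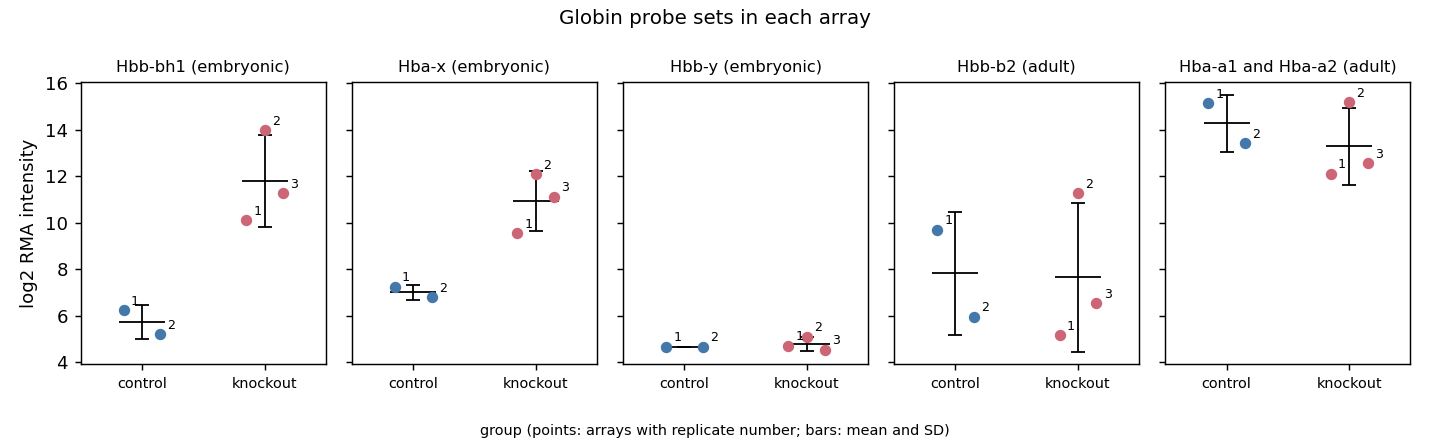
Log2 RMA intensity (y axis) of globin probe sets in 2 control and 3 knockout arrays, with points numbered by replicate and bars at mean and SD. Hbb-bh1 and Hba-x lay higher in each knockout array than in both controls, Hbb-y stayed below 5.77, and the adult globins overlapped between groups.

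Genes reported as repressed by LRF, a list of 5 that includes Hbb-bh1, had 3 members measured above the filter. Hbb-bh1 was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0153). Bcl2l11, which encodes the pro-apoptotic protein Bim, differed by 0.79 (SE 0.34; 0.32 to 1.26 without single arrays), and the Notch ligand gene Dll4 by 0.12 (SE 0.19). The list mean was 2.33 (camera adjusted p = 5.84e-05), with an adjusted p = 0.345 with an estimated correlation. Without control replicate 2 the mean was 1.95 and the camera call was lost; with no filter the mean was 1.43.

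Apart from the globins, the rule named 6 genes with higher and 8 with lower values in knockouts, and all had a limma adjusted p of 1. The largest of the higher ones were Trbv1, a T cell receptor beta variable segment (log2 difference 2.83, SE 0.56), and Rag1, the recombinase of antigen receptor genes (2.32, SE 0.47). Arpp21, a cAMP-regulated phosphoprotein, differed by 1.35 and Tmem87a by 1.42. Slc12a5, a potassium-chloride cotransporter, differed by 1.04 and the unnamed transcript 4921525O09Rik by 1.14. Of the lower ones, Ndnf, a secreted neurotrophic factor, had the smallest p (-2.04, SE 0.21; 7.004 ± 0.12 in 2 controls against 4.96 ± 0.28 in 3 knockouts). All 3 knockout values of Ndnf lay below 5.77, near background, so the size of its difference is uncertain, and the knockout mean of Cmbl (5.73) lay there too. Col14a1, a collagen chain, differed by -2.57 (SE 0.64) and the receptor tyrosine kinase Axl by -2.31 (SE 0.55). Cmbl, a hydrolase, differed by -1.24, the myosin light chain kinase Mylk by -1.09 and Spic, a transcription factor of red pulp macrophages, by -1.07. The palmitoyltransferase Zdhhc2 differed by -1.07 and the proteoglycan gene Sdc3 by -1.003, although only 1 of the 3 Sdc3 probe sets was lower.

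Notch targets lay higher than other genes as a list, with 8 of 13 measured members positive and a mean log2 difference of 0.43 (camera adjusted p = 6.81e-05). With an estimated correlation the adjusted p was 0.345, and 0 members passed over all genes or when adjusted over the list alone. That estimate was -0.011, below the preset 0.01, so the loss of the call did not come from a higher correlation of these members. Hes1, a transcriptional repressor and direct Notch target, was 7.17 ± 0.25 (SD, n = 2) in controls and 8.12 ± 0.21 (SD, n = 3) in knockouts, a difference of 0.95 (SE 0.21). Bcl11b, which commits precursors to the T lineage, differed by 2.20 (SE 0.75), Notch3 by 0.83 (SE 0.37) and Il2ra by 0.65 (SE 0.35). Notch3 reached 8.64 and 8.51 in knockout replicates 1 and 3 and 7.57 in replicate 2, against 7.38 and 7.44 in the controls. Members without a rise were Myc (-0.26), Nrarp (-0.065), Hey1 (-0.054), Heyl (-0.0098) and Hes5, which read 6.31 in every array. The list median was 0.32. The list's mean was 0.28 without knockout replicate 1. The receptor genes Notch1 (0.38, SE 0.47) and Notch3 were counted in the target list. Other components of the Notch pathway, such as the receptor gene Notch2 (0.33, SE 0.20) and ligand genes, had a mean of 0.033 over 18 genes and were not called (camera adjusted p = 0.111). They were called without knockout replicate 1 (0.072) and with the mean of a gene's probe sets (0.040, adjusted p = 0.0422).

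Lymphoid progenitor genes had 13 of 17 members positive and a mean of 0.80 (camera adjusted p = 3.34e-07; 0.345 as the adjusted p with an estimated correlation). Rag1 led this list. Cnn3 differed by 0.95 (SE 0.28), Il7r, the interleukin 7 receptor, by 2.34 (SE 0.98) and Ly6d by 0.95 (SE 0.46). Il7r was 9.35, 10.50 and 7.44 in knockout replicates 1, 2 and 3 and 6.21 and 7.30 in the controls; its protein was among those excluded by the sort. The list median relative to the control mean was 0.58 in knockout replicate 1 and 0.13 in replicate 3, and 1.36 higher in replicate 2 than in the other arrays. T lineage genes had 12 of 13 members positive and a mean of 0.41 (camera adjusted p = 0.000247, and adjusted p = 0.345 with an estimated correlation), a call lost without knockout replicate 2 (mean 0.43); the mean was 0.25 without knockout replicate 1. Bcl11b and Gata3 belonged to both the Notch target and the T lineage lists, and Cd6 differed by 0.48 (SE 0.19). B lineage genes had a mean of 0.50 (camera adjusted p = 0.00552, and adjusted p = 0.659 with an estimated correlation). Without knockout replicate 2 the list was called in the other direction (-0.37), and without either control the call was lost (0.54 without control 1 and 0.46 without control 2). Its mean was 0.94 without knockout replicate 1 and 0.93 without replicate 3. Blk, a kinase of B cells, read 7.43 in knockout replicate 2 and 5.34 to 5.96 elsewhere. The brightest B lineage member, Cd24a, differed by -0.032 (0.014 with cyclic loess), and the brightest T lineage member, the kinase gene Zap70, by 0.035.

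Stem cell genes were lower as a list, with 32 of 35 members negative and a mean of -0.64 (camera adjusted p = 5.84e-05). With an estimated correlation the adjusted p was 0.653. That estimate was 0.84, so the members moved together and their count is not one of independent genes. The list lay 2.07 lower in knockout replicate 2 than in the mean of the other arrays. Without that array the mean was -0.032, and without control replicate 2 it was -0.24, neither of which was called; without control replicate 1 it was -1.03 and without knockout replicate 3 it was -0.996. Selp, the adhesion molecule P-selectin, differed by -1.39 (SE 0.61), Cdkn1c, the cell cycle inhibitor p57, by -1.21 (SE 0.75), Sult1a1 by -0.96 (SE 0.57) and Pdzk1ip1 by -0.30 (SE 0.18). Hox genes and cofactors, 3 of which were also stem cell list members, had a mean of -0.38 (camera adjusted p = 0.00829, and adjusted p = 0.638 with an estimated correlation). Their mean was -0.037 without knockout replicate 2, -0.56 without control 1 and -0.21 without control 2, and none of these was called; it was -0.61 without knockout replicate 3. Megakaryocyte genes had 13 of 17 members negative and a mean of -0.37 (camera adjusted p = 0.00664, and adjusted p = 0.345 with an estimated correlation), with the platelet receptor subunits Gp1bb at -0.58 (SE 0.23) and Gp9 at -0.36 (SE 0.16) and the brightest member, Mmrn1, at -0.89 (-0.14 without knockout replicate 2). This call was lost without control replicate 1 (-0.38), and the mean was -0.23 without knockout replicate 2.

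Macrophage genes were lower in knockouts, with 14 of 14 members negative. Groups did not overlap for 11 of them (78.6%, against 20% by chance for a single gene in either direction). Members of this list moved together (estimated correlation 0.63), so these genes are not independent and their share cannot be judged by the 20%. The mean was -1.64 (camera adjusted p = 4.47e-17; adjusted p = 0.345 with an estimated correlation), and 0 members passed when adjusted over the list alone. Cd163, a scavenger receptor for haemoglobin, was 11.39 ± 0.92 (SD, n = 2) in controls and 8.29 ± 1.34 (SD, n = 3) in knockouts, a difference of -3.09 (SE 0.90). Axl and Spic were named above, and the complement gene C1qc differed by -2.02 (SE 0.61). The brightest members were Slc40a1, the iron exporter ferroportin (-0.75), and Vcam1, an adhesion molecule (-1.71). The list mean ranged from -2.08 to -1.19 as single arrays were left out. The list median relative to the mean of all arrays was 1.57 and 0.57 in controls 1 and 2. It was -0.975, -1.35 and 0.21 in knockout replicates 1, 2 and 3. The list median was thus 0.88 higher in control 1 than in control 2, while knockout replicate 3 differed from the control mean by -0.79. The list covers a cell type other than the one sorted, and whether its transcripts came from the LT-HSCs was not tested.

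Interferon response genes, which pIpC induces, had 32 of 32 members positive and a mean of 0.82 (camera adjusted p = 1.96e-12, and adjusted p = 0.487 with an estimated correlation). Members moved together (estimated correlation 0.79), so this count is not one of independent genes. The list median lay 1.92 above the control mean in knockout replicate 1 and 0.31 above it in replicate 3, and without replicate 1 the mean was 0.21. Mx1, an antiviral GTPase whose promoter drives the Cre transgene, read 10.77 in knockout replicate 1, 7.30 and 7.14 in replicates 2 and 3, and 5.47 and 6.32 in controls. Oasl2 differed by 1.71 (SE 0.87), Irf7 by 1.37 (SE 0.71) and Usp18 by 1.72 (SE 1.02).

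**Figure D2:**
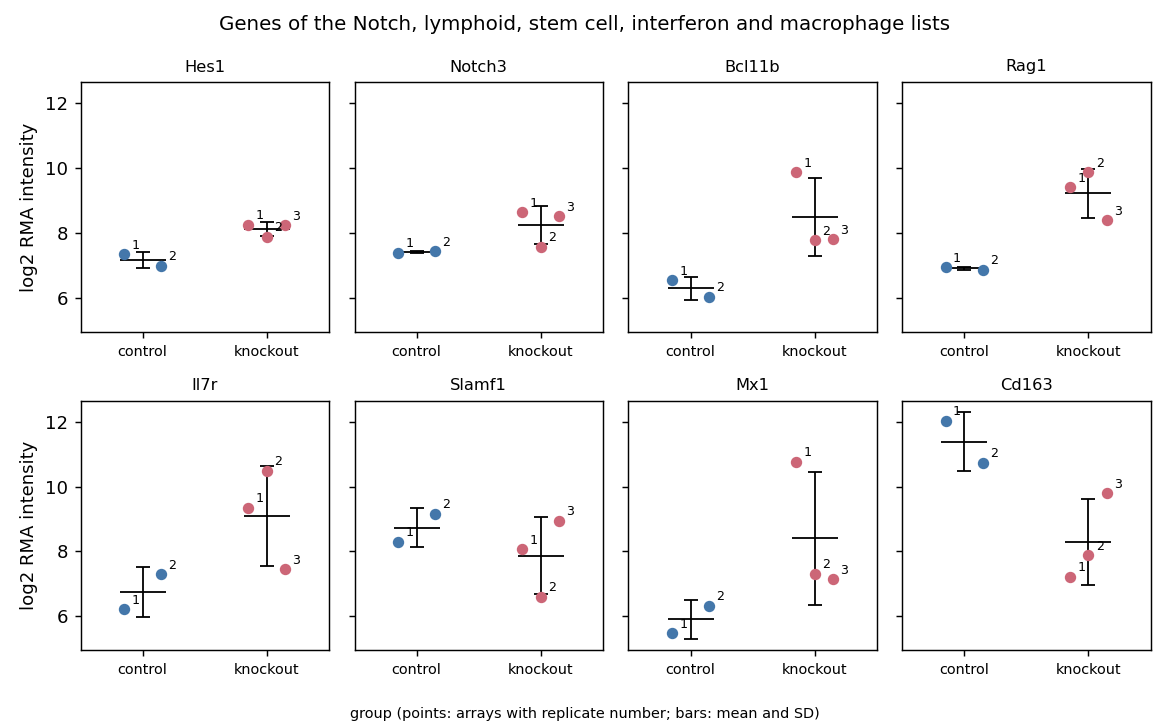
Log2 RMA intensity (y axis) of 8 genes in 2 control and 3 knockout arrays, with points numbered by replicate and bars at mean and SD. Hes1, Bcl11b and Rag1 lay higher and Cd163 lower in each knockout array than in both controls, Mx1 was highest in knockout replicate 1 (10.77) and Slamf1 lowest in knockout replicate 2 (6.60).

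Several lists stood out in knockout replicate 2. Immediate early genes lay 3.07 higher in that array than in the others, with Fos at 14.04 against 6.96 to 7.23, Klf4 at 11.95 against 5.96 to 6.33 and Atf3 at 10.31 against 5.46 to 6.28. Ier3, the member with the smallest p, read 10.52 there and 8.23 to 8.78 elsewhere. Their list mean was 0.89 (camera adjusted p = 0.000559; adjusted p = 0.638 with an estimated correlation). Without that array the list was called in the other direction (-0.25, adjusted p = 0.0493). The mean was 0.73 and not called without control replicate 2, 1.42 without knockout replicate 1 and 1.495 without replicate 3. Mast cell, basophil and eosinophil genes lay 2.45 higher there (list mean 0.82, camera adjusted p = 5.24e-05, and adjusted p = 0.345 with an estimated correlation) and were not called without that array (0.010), with a mean of 1.38 without knockout replicate 1. Cpa3, a mast cell protease, differed by 1.81 (SE 0.64) and the brightest member, the histidine decarboxylase gene Hdc, by -0.52. Granulocyte-monocyte progenitor genes lay 1.77 higher in it, and their list mean of 0.045 was not called (adjusted p = 0.231). It was called at -0.66 without that array, at 0.51 without knockout replicate 1 and at 0.29 without replicate 3, and was -0.20 without control 2. Mature neutrophil genes had a mean of -0.66 and were not called (adjusted p = 0.0569). They were called at -1.66 without knockout replicate 2 and at -1.499 without control 2, and their mean was 0.18 without control 1 and 0.21 without knockout replicate 1. They were also called with another eBayes prior (adjusted p = 0.0461), median centring (0.0223), the mean of a gene's probe sets (0.0377) and array weights (9.78e-08, at a mean of -2.14).

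Of the remaining lists, erythroid genes had a mean of 0.11 (camera adjusted p = 0.0452, and adjusted p = 0.708 with an estimated correlation). This became -0.63 without control replicate 2, 0.84 without control replicate 1, 0.31 without knockout replicate 1, -0.054 without knockout replicate 2 and 0.060 without knockout replicate 3, neither of the last 2 being called. The call was also lost with no filter (adjusted p = 0.195), cyclic loess (0.0569), median centring (0.0790), the mean of a gene's probe sets (0.0644), array weights (0.904, at a mean of -0.23) and the replicate block (0.161). Their brightest members were Car2 (0.26) and Ermap (0.58). Natural killer and innate lymphoid genes had a mean of 0.62 (camera adjusted p = 0.00257, and adjusted p = 0.346 with an estimated correlation), with the granule protease Gzma at 1.79 (SE 0.76) and the receptor gene Klrd1 at 2.19 (SE 1.38; 0.89 to 3.10 without single arrays) and Id2, the brightest member, at 0.35. Dendritic cell and MHC class II genes had a mean of 0.49 (camera adjusted p = 0.00291, and adjusted p = 0.487 with an estimated correlation). Without knockout replicate 2 these means were 0.27 and 0.26; without control 1 they were 0.53 and 0.39, without control 2 they were 0.71 and 0.59, and neither list was called in any of these. Without knockout replicate 3 they were 0.93 and 0.83. The dendritic cell call was also lost with no filter (adjusted p = 0.0552). Mitosis genes had a mean of -0.19 (camera adjusted p = 0.00234, and adjusted p = 0.659 with an estimated correlation), with Bub1b at -0.26 (SE 0.17) and Cdk1 at -0.23 (SE 0.17). It was 0.058 without control 1, -0.020 without knockout replicate 1 (neither called) and -0.44 without control 2. DNA replication genes also had a mean of -0.18 (camera adjusted p = 0.00291, and adjusted p = 0.653 with an estimated correlation), which was -0.037 without knockout replicate 2 and -0.088 without control 1, neither called; without control 2 it was -0.28 and without knockout replicate 3 it was -0.34.

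NF-kappaB targets had a mean of 0.38 (camera adjusted p = 0.00829, and adjusted p = 0.626 with an estimated correlation) and heat shock genes of 0.74 with a median of 0.24 (camera adjusted p = 0.0349, and adjusted p = 0.538 with an estimated correlation). The NF-kappaB mean was -0.026 without knockout replicate 2, 0.34 without control 1 and 0.43 without control 2, none of them called, and 0.63 without knockout replicate 3. The heat shock call was lost without control 1 (0.49), control 2 (0.98) or knockout replicate 1 (0.67), and with no filter (adjusted p = 0.107). Sex-linked genes had a mean of 1.80 over 4 genes (camera adjusted p = 0.00385, and adjusted p = 0.345 with an estimated correlation). Y-linked transcripts were low in control replicate 2, where Eif2s3y read 3.58, against 10.28 to 11.07 elsewhere. On 1 Xist probe set control 2 read 13.60, and control 1 and knockout replicate 1 read 4.15 and 4.21. Knockout replicates 2 and 3 read 11.21 and 11.92. Sex-linked RNA thus differed between arrays within both groups, and no fit held a term for sex. The camera call of this list therefore cannot be read as an effect of genotype. This call was lost without control replicate 2 (0.75) or knockout replicate 2 (1.87), and the mean was 2.84 without control 1. Lists that were not called had means of 0.78 for plasma cells, 0.14 for p53 targets, 0.019 for niche adhesion, 0.016 for oxidative phosphorylation, -0.015 for glycolysis, -0.055 for ribosome biogenesis, -0.066 for ribosomal proteins and -0.079 for endothelial and stromal genes. Without knockout replicate 2, camera called ribosome biogenesis (0.37), ribosomal proteins (0.17) and oxidative phosphorylation (0.15). Without knockout replicate 1 it called plasma cells (0.85), ribosome biogenesis (-0.29) and ribosomal proteins (-0.20), and without replicate 3 plasma cells (1.27) and p53 targets (0.21). The sign of the median or of the camera test differed from that of the mean for oxidative phosphorylation, glycolysis, ribosome biogenesis and endothelial and stromal genes.

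**Figure D3:**
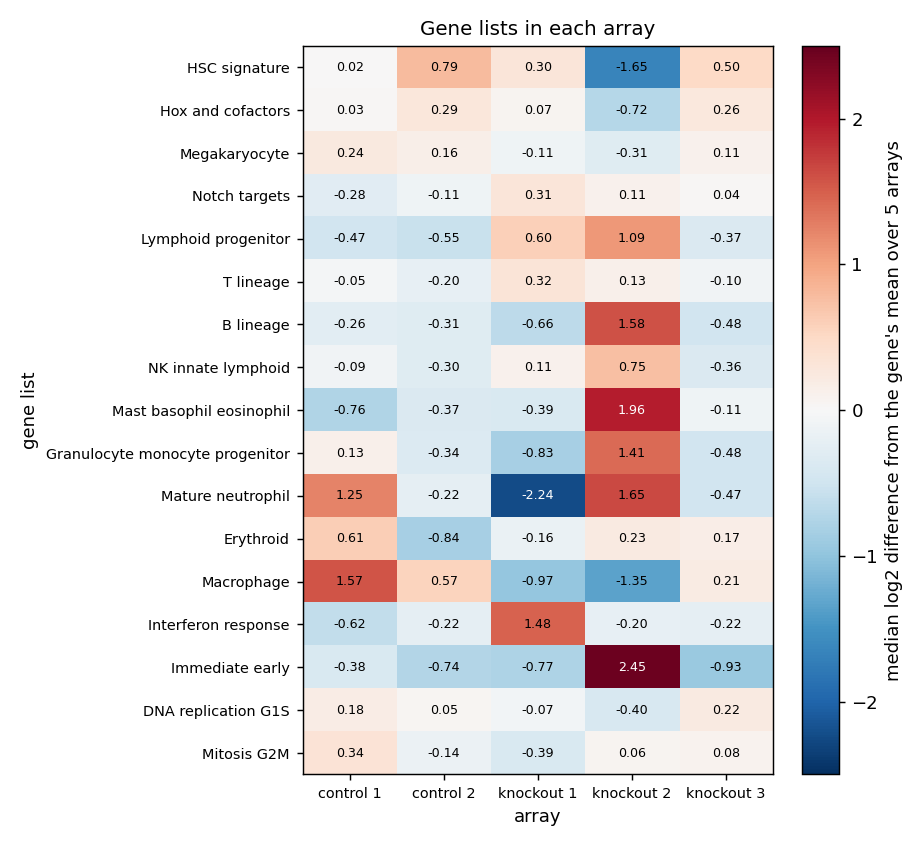
Median over each list's genes (rows) of the log2 difference between an array (columns) and the gene's mean over 5 arrays, shown by colour and printed value. Knockout replicate 2 was lowest for stem cell genes (-1.65) and highest for immediate early genes (2.45), and knockout replicate 1 was highest for interferon response genes (1.48).

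Over all probe sets, limma called 0 of 27022 at an adjusted p under 0.05 and 0 under 0.10, and 0 of 12813 genes. At an unadjusted p under 0.05 there were 306 probe sets (100 higher and 206 lower in knockouts), where 1351 would be expected with no difference. There were 17 candidates, 9 higher and 8 lower, and 2148 probe sets (7.95%) had groups that did not overlap, against 20% by chance. Without knockout replicate 2 the number of candidates was 63 and without replicate 3 it was 55; it was 10 without replicate 1, 37 without control 1 and 29 without control 2. Camera called 20 of 31 lists, 14 higher and 6 lower, and 0 with an estimated correlation or by fry. The higher ones include the sex-linked list, which cannot be read as an effect of genotype. The number called changed as single arrays were left out.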

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

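The counts of 0 changed probe sets and 0 changed genes, and the signs of the Zbtb7a (brightest probe set), Hbb-bh1 and Hba-x differences, held under every alternative in which they were computed. Not every alternative computed single genes, and the other 2 Zbtb7a probe sets differed by -0.36 and -0.05. All alternatives were fixed before the data were examined. The 17 candidates became 60 with array weights, 41 with the replicate block and 10 to 63 as single arrays were left out. The 20 called lists became 0 with an estimated correlation, 0 by fry, 22 with the replicate block and 11 to 23 without single arrays. Adjusted p-values with an estimated correlation and by fry were 0.345 and 0.611 for Notch targets (mean 0.43), 0.345 and 0.714 for lymphoid progenitor genes (0.80), 0.653 and 0.875 for stem cell genes (-0.64), 0.487 and 0.875 for interferon genes (0.82), and 0.345 and 0.611 for macrophage genes (-1.64). Array weights were 7.67 for knockout replicate 1, 1.03 for replicate 3, 0.787 for each control and 0.204 for knockout replicate 2, so that fit rests mostly on knockout replicate 1. It moved interferon genes to 1.81, mitosis to -0.46, neutrophil to -2.14, Notch target to 0.68 and T lineage genes to 0.66. It ended the calls of stem cell (-0.16), Hox (-0.15), NF-kappaB (0.059) and natural killer genes (0.50), and called neutrophil and oxidative phosphorylation genes (0.15). It turned Mpo to -0.47, Xist to -1.98, Notch components to -0.029, B lineage to -0.32, erythroid to -0.23, granulocyte-monocyte progenitor to -0.78, mast cell to -0.15, endothelial and stromal to 0.029, immediate early to -0.12, ribosomal protein to 0.18, ribosome biogenesis to 0.37 and niche adhesion genes to -0.18; of these lists, it called granulocyte-monocyte progenitor, ribosomal protein and ribosome biogenesis genes, and ended the calls of B lineage, erythroid, mast cell and immediate early genes. The mean of probe sets called Notch components (0.040), neutrophil (-0.66) and p53 target genes (0.15), and the replicate block called granulocyte-monocyte progenitor (0.29), plasma cell (1.27) and p53 target genes (0.21). These block means equal those without knockout replicate 3, so the block is no separate check of the differences. Neutrophil genes were also called with another eBayes prior and with median centring. Erythroid calls were lost with no filter, cyclic loess, median centring, mean probe sets and the replicate block, and dendritic cell and heat shock calls with no filter. With the lowest 60% left out, plasma cell genes and the genes reported as repressed by LRF had too few members for a test. Glycolysis turned to 0.029 with cyclic loess, 0.023 with median centring, 0.045 with mean probe sets and 0.049 with the replicate block. Cd24a turned to 0.014 with cyclic loess, 0.0057 with median centring and 0.0011 with the replicate block, and Id2 to -0.026 with array weights. Endothelial and stromal genes turned to 0.070 with the lowest 60% left out, and the mean of the genes reported as repressed by LRF was 1.43 with no filter. The replicate block also turned Xist to -0.69 and oxidative phosphorylation to -0.043. Replicate numbers were read as names of samples, since the labels state no pairing. Deviations from the group means correlated at -0.54 and -0.57 for equal numbers across groups. The deviations of 2 controls mirror each other, so these correlations cannot decide whether the numbers carry a pairing. Without single arrays, list means spanned -0.37 to 0.94 for B lineage, -0.21 to 0.10 for endothelial and stromal, -0.63 to 0.84 for erythroid, -0.17 to 0.074 for glycolysis, -0.66 to 0.51 for granulocyte-monocyte progenitor, -1.03 to -0.032 for stem cell, -0.25 to 1.495 for immediate early, -1.66 to 0.21 for neutrophil, -0.44 to 0.058 for mitosis, -0.026 to 0.63 for NF-kappaB, -0.14 to 0.14 for niche adhesion, -0.058 to 0.15 for oxidative phosphorylation, -0.23 to 0.17 for ribosomal protein and -0.29 to 0.37 for ribosome biogenesis genes. Single genes spanned -0.47 to 0.41 for Cd24a, -1.80 to 0.48 for Hdc, -0.17 to 0.74 for Id2, -0.15 to 0.22 for Zap70, -0.015 to 0.53 for Car2, -0.025 to 0.27 for Dll4, -0.46 to 7.03 for Eif2s3y, -0.23 to 1.40 for Ermap, -0.064 to 3.48 for Fos, -0.30 to 0.39 for Mpo, -0.77 to 0.029 for S100a8 and -2.54 to 3.17 for Xist. Of 66 single genes, these 12 turned and 27 more kept their sign but moved by over 1.5 times, among them 0.75 to 1.54 for 4921525O09Rik, 0.28 to 2.499 for Atf3, 0.32 to 1.26 for Bcl2l11, 0.061 to 0.95 for Blk, -0.37 to -0.15 for Bub1b, 0.26 to 0.70 for Cd6, -0.35 to -0.10 for Cdk1, -1.78 to -0.57 for Cdkn1c, 1.07 to 2.56 for Cpa3, 0.28 to 1.15 for Ier3, 0.40 to 0.93 for Il2ra, 0.73 to 1.84 for Irf7, 0.24 to 3.07 for Klf4, 0.89 to 3.10 for Klrd1, 0.58 to 1.26 for Ly6d, -1.29 to -0.14 for Mmrn1, 1.32 to 3.14 for Mx1, -1.16 to -0.046 for Ngp, 0.98 to 2.36 for Oasl2, -0.37 to -0.18 for Pdzk1ip1, -2.08 to -0.71 for Selp, -1.08 to -0.38 for Slc40a1, -1.25 to -0.42 for Sult1a1 and 0.75 to 2.20 for Usp18. A lone control was assumed to vary like the knockouts. The cause of these shifts was not tested. The 40% of probe sets with a mean log2 value below 5.77 were taken as near background, where real differences can be compressed. This level is the cut of the filter, and background was not measured for single probe sets.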

Other observations

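The tests of progenitor cells, RNA length, erythroid genes array by array, sex of the mice, adult globin signal and other splits below were chosen after their results had been seen; those of the erythroid list between groups and of cycling cells were not.

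Some transcripts of mature neutrophils read near the top of the scale in these stem cell libraries. S100a8, a calcium-binding protein of neutrophil granulocytes, read 15.09 and 14.43 in controls and 13.51, 15.11 and 14.46 in knockout replicates 1, 2 and 3, on a scale that ended at 15.19 to 15.29. Ngp, a granule protein, read 15.04, 14.18, 12.80, 15.01 and 14.11 in the same order. Other members of the list read lower, such as Mmp8 at 6.95 and Itgam at 4.42 in knockout replicate 1, the array where the list median was lowest. Levels of different probe sets cannot be compared directly. The neutrophil list median was 1.65 higher in control 1 than in control 2, and in knockout replicate 1 its difference from the control mean was -2.62. The bright probe set shared by Hba-a1 and Hba-a2 was highest in the same arrays, control 1 (15.13) and knockout replicate 2 (15.19), as was that shared by the adult beta globins (14.88 and 15.02). A dim probe set of Hbb-b2 was lowest there (6.05 and 5.76, against 6.71 to 7.26).

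Transcripts of some sort markers, chosen after their values were seen, set knockout replicate 2 apart as well. Slamf1, which encodes CD150, read 6.60 there and 8.06 to 9.16 elsewhere. Cd48 read 9.97 against 7.87 to 8.59, and Kit, the stem cell factor receptor, 9.60 against 11.12 to 11.82. Flt3 did not stand apart (8.56 against 8.25 to 9.50), and Il7r was high there (10.50) and in knockout replicate 1 (9.35). Mpo, the myeloperoxidase of granulocyte precursors and the brightest member of the granulocyte-monocyte progenitor list, read 13.89 against 12.50 to 13.22. The inducible heat shock gene Hspa1a read 12.96 there and 5.38 to 7.03 elsewhere. The heat shock list as a whole did not move with it: its median difference from the mean of the other arrays was -0.30 in knockout replicate 2.

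The embryonic globins were higher in all 3 knockout arrays, while the 22 erythroid genes measured had a median log2 difference of 0.17 (95% bootstrap interval over genes 0.018 to 0.26), a value that leaves out the spread between arrays: the list mean was -0.63 without control 2 and 0.84 without control 1. Erythroid cells in the sort would bring their other abundant transcripts, but control 1 had the highest erythroid list median (0.61 from the mean of all arrays, against -0.16, 0.23 and 0.17 in knockouts) and the embryonic globins stayed low in it, which argues against more erythroid cells alone. Cross-hybridisation of adult beta globin is argued against by knockout replicates 1 and 3, where its bright shared probe set read 12.17 and 13.28, against 14.88 and 13.38 in controls, and the brightest of Hbb-bh1 still read 10.11 and 11.26, against 6.23 and 5.20; the smallest difference from control 1 over its 3 probe sets, 1.59, and the lowest group difference, 3.78, which missed an earlier bound of 4 that the other 2 met, come from a probe set near background in controls (4.92), so their sizes are uncertain. Within each group, however, Hbb-bh1 ranked with adult beta globin, as cross-hybridisation would also give (knockout replicates 1, 3 and 2 read 12.17, 13.28 and 15.02 for the shared probe set and 10.11, 11.26 and 13.97 for Hbb-bh1), and the dim Hbb-b2 probe set was higher in knockout replicates 1 and 3 (6.80 and 7.26), so it is argued against as the source of the difference between the groups and not of the spread within them. The hypothesis left open is that loss of Lrf, a known repressor of embryonic and fetal globin genes, may raise these transcripts, in the sorted cells or in red cell RNA carried with them. The lists of embryonic globins and of genes reported as repressed by LRF were fixed before the data were examined, so the group difference was tested. No member passed over all probe sets. What caused the difference, and which cells carried the RNA, was not tested.

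Knockout replicate 2 stood apart from the other arrays. Cycling cells are argued against by the mitosis list, which lay 0.074 higher in it, and the DNA replication list, at -0.50. Cells outside the gate may contribute, since the granulocyte-monocyte progenitor list lay 1.77 higher and the stem cell list lower (-2.07); the gate should exclude such cells, 22 of the list's 24 genes were above the filter in these libraries, and Nkg7 is also in the natural killer list. Differently amplified RNA stays open too, with the Actb 3' to 5' difference at 3.85, outside the range of the other arrays. Macrophage genes differed from the other arrays by -1.68 in it, so other cell types did not all move one way.

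Knockout replicates 2 and 3 carried both Xist, the RNA of the inactive X chromosome in females, and Y-linked transcripts. On 1 Xist probe set they read 11.21 and 11.92, against 13.60 in control 2 and 4.15 and 4.21 in control 1 and knockout replicate 1, and Eif2s3y read 10.75 and 10.28 in them. RNA of male and female mice in one library stays open as an explanation. That 2 of 5 arrays lay above the midpoint of the controls for both transcripts is the pattern itself and gives it no support. A second Xist probe set read 7.37 in knockout replicate 2, below its controls' mean of 8.91, but above control 1 (6.02) and knockout replicate 1 (5.59). It read 10.29 in knockout replicate 3. The brightest Xist probe set read 11.42 and 12.47 in knockout replicates 2 and 3. It read 13.01 in control 2, and 7.30 and 7.51 in control 1 and knockout replicate 1. The description of knockout replicate 3 named 2 animals and that of knockout replicate 2 named 1. An increase of Xist after loss of Lrf in every knockout library is argued against by knockout replicate 1, where Xist was about as low as in control 1 on each probe set. On the first probe set both read near background, so their difference of 0.054 has no meaning as a size. No biological explanation of a mixed library was tested.

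Among the 10 splits of the arrays into 2 and 3, 8 gave at least the 17 candidates of the real split, and the highest other gave 1080. The splits are too few for a share under 0.05. The split with 1080 set control 1 and knockout replicate 2 against the rest, which points to a structure of the samples that runs across the genotypes.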
